A study of Mus musculus with 6 samples.

How the data were processed

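The series holds 6 libraries of mouse gastrocnemius, 3 control and 3 restraint, grouped by the treatment label, with replicate numbers from the titles. Per the submitters' processing notes, bcl2fastq 2.20.0, Trimmomatic, HISAT2 2.1.0 and StringTie 2.1.3b were used with GRCm38 (mm10), with no role or order given. The deposited table holds whole read counts per feature, per the file headers, with 1 column per library. It also holds FPKM and TPM made by the authors, per the file headers. The use of strand in counting is not given in the sources used here, so reads of overlapping antisense genes, such as Foxo6 and its antisense partner, could not be told apart.

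Of 46504 features, 45679 carry a gene identifier and symbol and 825 are unannotated loci with an identifier but no symbol. These loci took 4.84% to 7.14% of counts per library, and a single locus took 4.21% to 6.31%. They were kept as features in tests and library sizes, since each has its own identifier. The fixed plan left rows that name no gene out of both. An alternative leaves these loci out together with mitochondrial genes. The 10 most abundant features took 27.8% to 32.0% of counts, and mitochondrial genes 13.2% to 19.3%, highest in control 2. Coordinates are those of the RefSeq gene table on GRCm38.p6, where 45581 identifiers matched.

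Counts were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr with a minimum count of 10 and a minimum total of 15, TMM factors, glmQLFit, glmQLFTest, two-sided) with Benjamini-Hochberg adjustment at 0.05 and no fold limit. SE is the size of the log2 fold change divided by the square root of the F statistic. CPM are scaled by TMM. Gene lists, 36 in all, were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, with adjustment over the lists; fry tested each list on its own. Apart from the keeping of unannotated loci, the lists, tests, alternatives and rule for named genes were fixed before the data were examined. The rule names the 10 largest rises and falls among calls whose groups do not overlap, with average log2 CPM of at least 1 and no predicted, clone, mitochondrial, unannotated or pseudogene name; at most 4 called members per list by smallest p, or up to 2 with no call; and a fixed panel: Fkbp5, Tsc22d3, Pdk4, Trim63, Fbxo32, Per1, Il6, Ccl2, Mstn and Ppargc1a. List members named beyond these, single-library values and the genes of the closing section outside this rule were chosen after their values were seen. Single values of some list members are not reported here.

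Alternatives were DESeq2 size factors, upper quartile factors and library totals; no filter and a stricter filter (1 CPM in every library of a group and a mean of 10 counts); DESeq2 1.42.0 and limma voom; limma on log2 of FPKM or TPM with a pseudocount of 1 or 0.1, for features of at least 1 in 3 libraries; robust dispersion; a replicate block; leaving out unannotated loci and mitochondrial genes, or the 10 most abundant features; a minimum fold of 1.2; and each library left out. Total counts between 44290720 and 51125779 put 3 counts, the floor used for a feature at 0, at 0.0551 to 0.0731 CPM per library, which covers counting error only. No pair of libraries in a group agreed within sampling noise: chi-square per degree of freedom was 27.2 or more.

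The edgeR script was tested on simulated counts with the real means, library sizes and dispersions for this comparison, over 15208 features. It recovered 10.8% of 65 genes changed by 1.5-fold, 60% of 65 changed by 2-fold and 86.2% of 65 changed by 4-fold, and 12 of its 114 calls (10.5%) were false, above the nominal share. In the same data 19.7% of DESeq2 calls and 9.17% of voom calls were false. The counts were a single draw with genes independent, so these shares do not measure a long-run error rate.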

Results

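PolyA RNA of mouse gastrocnemius, the main calf muscle, was measured in 3 control libraries and 3 libraries of mice held in 50 mL tubes for 3 h every 4 days. Both groups carry the label day 4. The title of the series names the interaction of skeletal muscle with neuroinflammation under this stress. Total counts were 48155940, 44814050 and 51125779 in controls 1 to 3 and 44907513, 44973655 and 44290720 in restraint 1 to 3. Of 46504 features in the table, 23147 had at least 1 count and 15448 were tested. The labels do not say that each library came from another mouse, so p-values measure the spread between these libraries, which may be technical.

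Lists of heat shock, atrophy, denervation and neuromuscular junction, immediate early and cyclic AMP genes were higher in restraint than in control. Interferon-stimulated genes were lower. Fry and camera with a preset correlation called these 6 lists, and camera with an estimated correlation did not. Glucocorticoid-responsive genes were higher by camera with the preset correlation only. With that correlation another split of the 6 libraries called 17 lists, against 16 for the real one. Single clock and growth-related genes moved both ways. Atf3, a stress-induced transcription factor, rose from 1.99 ± 0.709 to 37.1 ± 11.9 CPM (mean ± SD, n = 3 per group), a log2 fold change of 4.21 ± 0.32 (SE) with an edgeR adjusted p of 0.0015. Nr4a3, an orphan nuclear receptor induced early after stimulation, rose from 1.67 ± 0.768 to 31.8 ± 10.7 CPM. Nr1d1, the clock repressor REV-ERBα, fell from 105.1 ± 5.69 to 27.7 ± 7.83 CPM, a log2 fold change of -1.92 ± 0.18 with an edgeR adjusted p of 0.0044. Igfbp5, a binding protein of insulin-like growth factors, fell from 496 ± 70.9 to 165 ± 25.4 CPM.

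**Figure D1:**
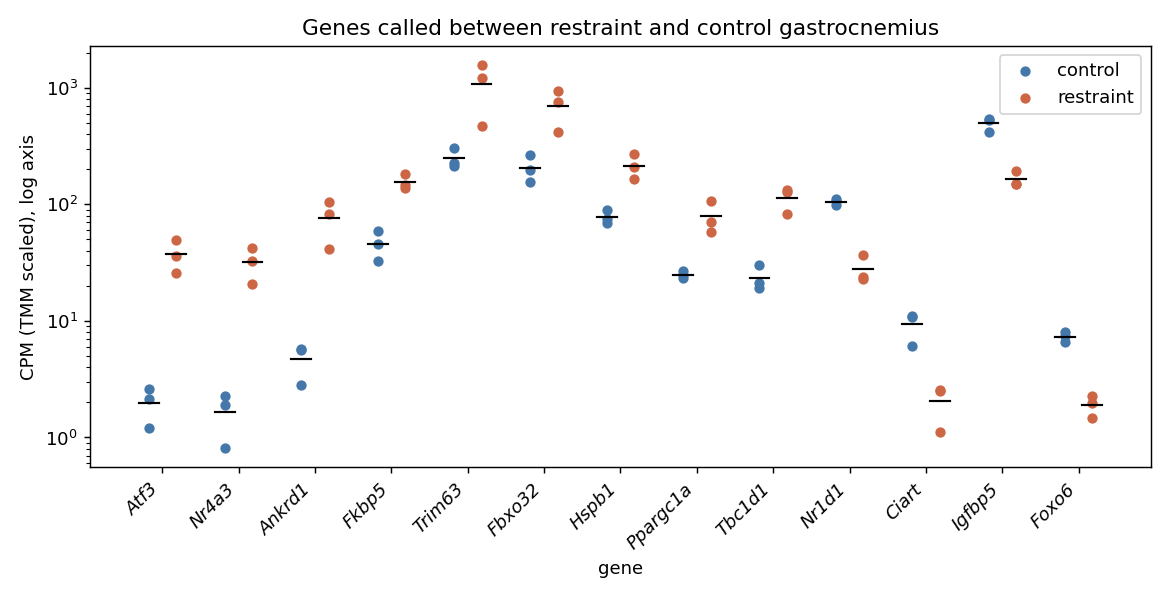
CPM on a log axis for 13 genes called between the groups, with 1 point per library (3 control, 3 restraint) and a line at each group mean. For each gene shown the restraint points lie apart from the control points and Trim63 stands at 469.7 CPM in restraint 1 against 1563 and 1201 CPM in restraint 2 and 3.

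The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 282 features, 195 higher and 87 lower in restraint. They held 233 protein-coding genes, 26 lncRNAs, 4 pseudogenes and 18 unannotated loci. Of the calls, 119 were higher and 40 lower by over 2-fold. Groups did not overlap for 3360 tested features, or 21.8%, where chance gives 10%. Leaving out control 1 brought the count to 16, control 2 to 51, control 3 to 174, restraint 2 to 98 and restraint 3 to 55, while 350 were called without restraint 1. Of the 282 calls, 15, 47, 126, 213, 92 and 51 were called again without control 1, control 2, control 3, restraint 1, restraint 2 and restraint 3.

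**Figure D2:**
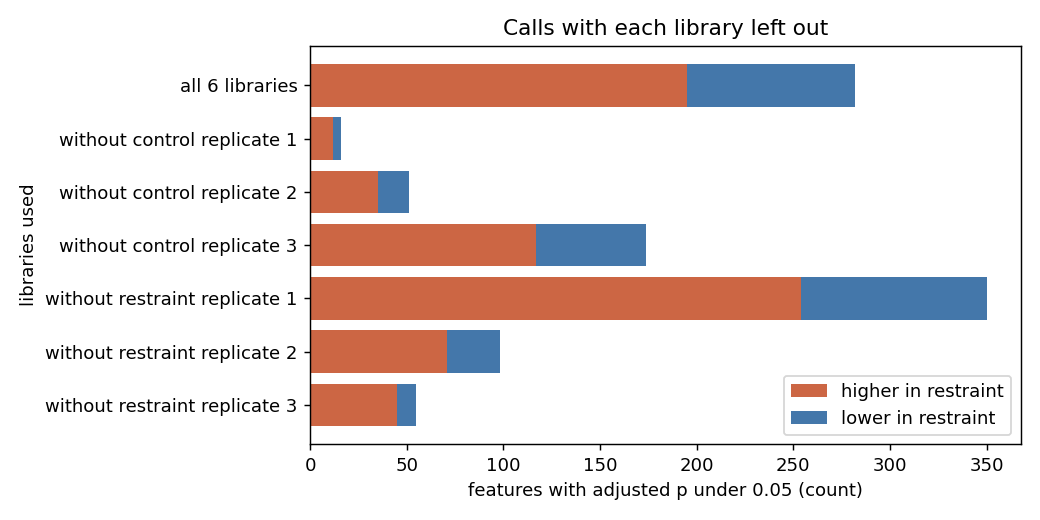
Number of features called (horizontal axis, count) with all 6 libraries and with each library left out, as stacked bars of higher and lower calls. The count is 282 with all libraries, 16 without control 1 and 350 without restraint 1.

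The 10 largest rises by the fixed rule were Krt8, Nr4a3, Atf3, Ankrd1, Mustn1, Rrad, Mt2, Cd68, Tnfrsf12a and Tiam2, with log2 fold changes from 4.28 to 2.41 for all but Krt8. Krt8, an epithelial-type keratin, stood at 0.0817, 0 and 0 CPM in controls 1 to 3, about the level of 3 counts or below it, and at 0.719, 6.88 and 6.78 CPM in restraint 1 to 3. Its fitted log2 fold change of 7.30 is therefore poorly fixed: it ran from 6.68 to 10.78 with each library left out (10.78 without control 1), and only the fit without restraint 1 called it. Tnfrsf12a, the receptor of the cytokine TWEAK, rose from 6.56 ± 0.35 to 45.3 ± 10.1 CPM, by 2.78 ± 0.17 on the log2 scale. Mustn1, a gene of the musculoskeletal system, rose from 29.8 ± 5.40 to 336 ± 179 CPM. The 10 largest falls were Ciart, Foxo6, Nr1d1, Ighm, Tnfaip2, Igfbp5, Nrep, Lrrc38, Cited4 and Metrn, from -2.18 to -1.37. Foxo6, a forkhead transcription factor, fell from 7.30 ± 0.709 to 1.91 ± 0.40 CPM. Without control 1, control 2, control 3, restraint 1, restraint 2 and restraint 3, the 10 rises kept 4, 6, 7, 10, 7 and 7 calls and the 10 falls kept 3, 5, 9, 9, 8 and 3. On GRCm38, Atf3 (gene 11910) lies on chromosome 1 from 191170296 to 191183333, Nr4a3 (gene 18124) on chromosome 4 from 48045078 to 48086447 and Nr1d1 (gene 217166) on chromosome 11 from 98767932 to 98775377.

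Glucocorticoid-responsive genes were higher as a list: 5 of 25 tested members passed over all genes, all higher, and 18 rose and 2 fell when adjusted over the list alone. The list's camera adjusted p was 1.66e-07 with a median log2 fold change of 0.82, against adjusted p = 0.415 with an estimated correlation and 0.101 by fry. Fkbp5, a co-chaperone of the glucocorticoid receptor, rose from 45.7 ± 13.1 to 155 ± 23.0 CPM (n = 3 per group), by 1.77 ± 0.21 on the log2 scale. The metallothioneins Mt1 and Mt2 rose by 2.06 ± 0.31 and 2.99 ± 0.50, and Mknk2 by 0.87 ± 0.15. Tsc22d3, encoding GILZ, had a log2 fold change of 0.90 ± 0.21 and Pdk4, a kinase that inhibits pyruvate dehydrogenase, 1.36 ± 0.37, with edgeR adjusted p of 0.0754 and 0.114. Its 5 gene calls numbered 1, 0, 2, 5, 2 and 1 without control 1, control 2, control 3, restraint 1, restraint 2 and restraint 3.

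Atrophy and ubiquitin-autophagy genes were also higher, with 5 of 25 members past the test over all genes and 13 adjusted over the list alone, all higher. The list's camera adjusted p was 1.65e-07, against adjusted p = 0.283 with an estimated correlation. Trim63, the ubiquitin ligase MuRF1, rose from 249 ± 50.4 to 1078 ± 557 CPM, by 2.11 ± 0.38 on the log2 scale (edgeR adjusted p = 0.0316), with 469.7, 1563 and 1201 CPM in restraint 1 to 3. Fbxo32, the ubiquitin ligase atrogin-1, rose by 1.77 ± 0.30, Map1lc3a, an autophagosome protein, by 0.91 ± 0.13 and Eif4ebp1, a repressor of translation initiation, by 1.08 ± 0.16. Mstn, encoding the growth inhibitor myostatin, had a log2 fold change of 0.12 ± 0.11 and did not pass. All 31 proteasome subunits had positive log2 fold changes with a median of 0.20, and Psmd11 passed over all genes at 0.56 ± 0.11, with 4 adjusted over the list alone. Psmd11 is also a member of the atrophy list and among its 5 calls. The proteasome list had a camera adjusted p of 4.39e-07, and adjusted p = 0.462 with an estimated correlation. The atrophy list's median of 0.41 was 0.23 without restraint 2. The 5 atrophy calls numbered 0, 1, 2, 5, 2 and 0 without control 1, control 2, control 3, restraint 1, restraint 2 and restraint 3, and of the 6 fits with a library left out only that without restraint 1 called Psmd11.

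Immediate early and cyclic AMP response genes rose in part. Of 21 immediate early genes tested, 5 rose over all genes and 9 adjusted over the list alone: Atf3, Nr4a3, Ccn1 by 1.83 ± 0.26, Jun by 1.25 ± 0.19, and Maff among the 5. Of 18 cyclic AMP and adrenergic genes, 6 rose and 1 fell over all genes, and 8 rose and 2 fell adjusted over the list alone. Nr4a3 is a member of both lists and counts among the calls of each. Ppargc1a, a coactivator of mitochondrial biogenesis, rose from 24.8 ± 1.73 to 79.0 ± 25.4 CPM, by 1.67 ± 0.21 on the log2 scale, Sik1, a salt-inducible kinase, by 1.72 ± 0.25 and Vgll2, a muscle transcription cofactor, by 0.96 ± 0.10. Amd1, an enzyme of polyamine synthesis, was the member that fell. The camera adjusted p was 1.65e-07 and 0.00015 for the 2 lists, and adjusted p = 0.283 for both with an estimated correlation. The median of immediate early genes was 0.37, and 0.63 without control 2. Without control 1, control 2, control 3, restraint 1, restraint 2 and restraint 3, calls numbered 2, 2, 2, 5, 3 and 2 for immediate early genes and 1, 2, 6, 5, 4 and 3 for cyclic AMP genes.

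Denervation and neuromuscular junction genes were higher, with 6 of 20 tested members past the test over all genes and 10 adjusted over the list alone. The list's camera adjusted p was 1.77e-06, against adjusted p = 0.283 with an estimated correlation. Ankrd1, a stress-responsive ankyrin repeat protein of muscle, rose from 4.73 ± 1.66 to 76.0 ± 32.0 CPM, by 4.01 ± 0.39 on the log2 scale. Myog, the myogenic factor myogenin, rose by 2.23 ± 0.37, Musk, the receptor kinase of the junction, by 0.94 ± 0.12 and Chrnb1, a subunit of the acetylcholine receptor, by 0.81 ± 0.09. Myog was also the 1 call among 12 satellite cell and myogenic genes, of which 3 rose adjusted over the list alone. The myogenic list had a camera adjusted p of 0.0357, and adjusted p = 0.415 with an estimated correlation. With controls 1 to 3 and then restraint 1 to 3 left out, the 6 denervation and junction calls numbered 1, 2, 3, 6, 3 and 2. Only the fit without restraint 1 called Myog. The myogenic list missed the camera threshold without control 3 (adjusted p = 0.104) and without restraint 2 (0.0814).

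Heat shock and chaperone genes were higher: 5 of 18 rose over all genes, and 9 rose and 1 fell adjusted over the list alone. The list's camera adjusted p was 1.93e-06, against adjusted p = 0.283 with an estimated correlation. The small heat shock genes Hspb1 and Hspb7 rose by 1.47 ± 0.18 and 1.55 ± 0.24 on the log2 scale, Cryab, the chaperone alpha B-crystallin, by 1.01 ± 0.18 and Dnaja4 by 0.65 ± 0.11. The fifth call, Hspa1b, has a near-identical neighbour, Hspa1a, so the split of reads between them is uncertain. Of 24 unfolded protein and integrated stress response genes, Mthfd2, a mitochondrial folate enzyme, rose by 1.09 ± 0.22, and 3 rose adjusted over the list alone. The unfolded protein list had a camera adjusted p of 0.0827, and adjusted p = 0.415 with an estimated correlation. By fry it passed, higher, with an adjusted p of 0.0319. The 5 heat shock calls numbered 0, 1, 3, 5, 1 and 2 without control 1, control 2, control 3, restraint 1, restraint 2 and restraint 3, and only the fit without restraint 1 called Mthfd2.

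**Figure D3:**
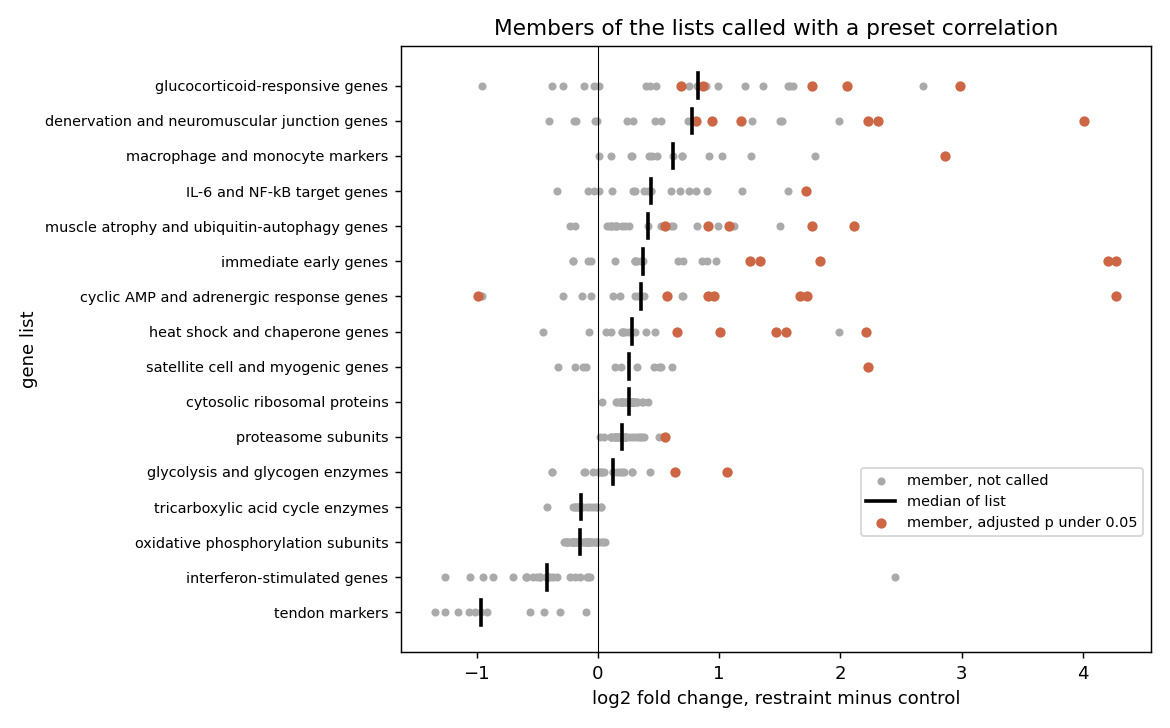
Log2 fold change of restraint minus control (horizontal axis) for each tested member of the 16 lists called by camera with a preset correlation, with a line at each list's median. Medians run from -0.96 for tendon markers to 0.82 for glucocorticoid-responsive genes, and coloured points are members called over all genes.

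Genes of energy metabolism gave 2 calls. Of 22 glycolysis and glycogen genes, Fbp2, the muscle fructose bisphosphatase, rose by 1.06 ± 0.17 on the log2 scale and Phka1, a subunit of phosphorylase kinase, by 0.64 ± 0.10, the same 2 adjusted over the list alone. No member passed among 42 oxidative phosphorylation subunits, 17 tricarboxylic acid cycle enzymes, 28 fatty acid genes or 20 lipid synthesis genes by edgeR over all genes; adjusted over the list alone, 2 fatty acid genes rose and 3 fell and 1 lipid synthesis gene fell. Oxidative phosphorylation and cycle genes had median log2 fold changes of -0.15 and -0.14. Idh2 had -0.42 ± 0.14, Cyc1 -0.26 ± 0.12, Hadh -0.38 ± 0.09, Ucp3 0.98 ± 0.23 and Thrsp -0.59 ± 0.13, none past the test. Camera adjusted p was 0.0331 for glycolysis (higher), 0.00939 for oxidative phosphorylation (lower) and 0.0362 for the cycle (lower), and adjusted p = 0.676, 0.847 and 0.84 with an estimated correlation. Oxidative phosphorylation missed the camera threshold without control 1 (0.169), control 2 (0.212) and restraint 2 (0.0727), with medians from -0.25 without control 3 to -0.057 without control 2. The median of the cycle was -0.071 without control 1 and -0.077 without restraint 3. Glycolysis missed it without control 1 (0.0563), control 3 (0.0824), restraint 1 (0.214) and restraint 2 (0.0768), and the cycle without control 1 (0.148), control 3 (0.0832) and restraint 3 (0.529) and with library totals only (0.0764). The fatty acid and lipid synthesis lists had camera adjusted p of 0.23 and 0.143, and lipid synthesis 0.0328 (lower) without restraint 1. The 2 glycolysis calls numbered 0, 0, 1, 1, 1 and 0 without control 1, control 2, control 3, restraint 1, restraint 2 and restraint 3.

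Insulin and growth signalling genes moved both ways, with 2 of 20 higher and 2 lower over all genes, and 2 higher and 3 lower adjusted over the list alone. Tbc1d1, a regulator of glucose transporter traffic, rose from 23.5 ± 6.08 to 114 ± 27.3 CPM, by 2.27 ± 0.23 on the log2 scale, and Eif4ebp1 also rose. Igfbp5 fell by 1.59 on the log2 scale and Grb14, an inhibitor of the insulin receptor, by 0.93. The list as a whole had a camera adjusted p of 0.796. Its 4 calls numbered 1, 2, 3, 4, 4 and 2 without control 1, control 2, control 3, restraint 1, restraint 2 and restraint 3.

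Circadian clock genes moved in both directions: of 19 tested, 3 rose and 2 fell over all genes, and 6 rose and 8 fell adjusted over the list alone. Nr1d1 and Ciart, a repressor of the clock, fell, Ciart from 9.33 ± 2.78 to 2.07 ± 0.825 CPM. Nfil3, a repressor of D-box genes, rose by 1.18 ± 0.12 on the log2 scale and the nuclear receptor Rora by 0.69 ± 0.11. Per1, a light- and glucocorticoid-induced clock gene, had a log2 fold change of -0.96 ± 0.28 and an edgeR adjusted p of 0.142. The list had a camera adjusted p of 0.714, and the labels give no time of day for tissue collection. Its 5 calls numbered 1, 2, 3, 4, 3 and 2 without control 1, control 2, control 3, restraint 1, restraint 2 and restraint 3.

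Fibre type genes showed no common direction. None of 15 fast fibre genes passed by edgeR, over all genes or adjusted over the list alone, and Casq1, calsequestrin of fast fibres, had a log2 fold change of -0.43 ± 0.12. Of 15 slow fibre genes, Ankrd2, Csrp3 and Fhl1, which also respond to stretch, rose by 1.08 ± 0.18, 2.16 ± 0.40 and 1.02 ± 0.19, while 1 other member fell adjusted over the list alone; the list's median was -0.13, turning to 0.10 without control 2, and its mean 0.19. Camera adjusted p was 0.638 and 0.648. All 35 cytosolic ribosomal proteins had positive log2 fold changes with a median of 0.25, none past the test over all genes or adjusted over the list alone, and Rpl3 had 0.36 ± 0.12. The median was 0.12 without control 3 and 0.16 without restraint 3. That list had a camera adjusted p of 1.32e-06 and adjusted p = 0.676 with an estimated correlation. The 3 slow fibre calls numbered 0, 0, 2, 3, 0 and 0 without control 1, control 2, control 3, restraint 1, restraint 2 and restraint 3.

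Inflammatory genes gave few calls. None of 11 tested cytokines and chemokines passed by edgeR over all genes, with 2 higher and 4 lower adjusted over the list alone. Ccl2 had a log2 fold change of 0.13 ± 0.49, Cxcl10 2.45 ± 0.60 and Ccl11 -0.41 ± 0.10. Ccl2 and Cxcl10 were counted at low levels, with means of 0.200 and 0.174 CPM in controls and 0.217 and 0.960 CPM in restraint. Il6 had too few counts to be tested. Of 19 IL-6 and NF-kB targets, Pim1, a kinase induced by cytokines, rose by 1.72 ± 0.31 and 5 rose adjusted over the list alone. Of 26 interferon-stimulated genes 25 had negative log2 fold changes, with a median of -0.42. None passed over all genes, and 1 rose and 3 fell adjusted over the list alone. Cxcl10 was the member that rose. Gbp3 had -0.95 ± 0.21. Of 16 antigen presentation genes, 1 fell adjusted over the list alone and none passed over all genes; Psmb8 had -0.68 ± 0.17. Camera adjusted p was 0.000295 for the IL-6 list (higher) and 5.37e-07 for interferon genes (lower), and adjusted p = 0.415 and 0.283 with an estimated correlation; cytokines and antigen presentation had 0.65 and 0.439. Of the 15 myokines tested, none passed over all genes and 3 fell adjusted over the list alone; Igf1 stood at 18.6 ± 4.50 CPM in controls and 9.28 ± 1.79 in restraint, an edgeR adjusted p of 0.0512, and the list a camera adjusted p of 0.21. The IL-6 list's median of 0.43 was 0.24 without restraint 2. With a library left out, Pim1 was called only without restraint 1 and without restraint 3.

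Markers of other cell types differed between libraries as well as groups. Of 15 macrophage markers, Cd68 rose by 2.86 ± 0.56 on the log2 scale, with 2.29, 13.6 and 11.5 CPM in restraint 1 to 3, and with a library left out it was called only without restraint 1; the list's camera adjusted p was 0.00196, and adjusted p = 0.676 with an estimated correlation. Without restraint 2 its median fell from 0.62 to 0.21 and the call was lost (adjusted p = 0.14). All 11 tendon markers had negative log2 fold changes with a median of -0.96, none past the test over all genes and 7 lower adjusted over the list alone; Kera, encoding the proteoglycan keratocan, had -1.34 ± 0.35. Their camera adjusted p was 2.27e-05, and adjusted p = 0.415 with an estimated correlation. Of 2 lymphocyte markers tested Ighm, an immunoglobulin heavy chain, fell by 1.80 on the log2 scale, with a library left out was called only without control 3 and without restraint 1, and 1 rose and 1 fell adjusted over the list alone. Among 28 extracellular matrix genes 1 fell adjusted over the list alone, and Col1a1 stood at 34.5, 140.6 and 60.0 CPM in restraint 1 to 3 against 159 ± 9.39 in controls. Over all genes edgeR called none of the 3 neutrophil, 15 endothelial, 15 fibroblast, 12 smooth muscle, 13 adipocyte, 14 Schwann, 7 erythroid and 15 cell cycle genes tested, and adjusted over the list alone it called only 2 neutrophil markers, both higher. Camera adjusted p was 0.0709 for neutrophil markers, 0.284 for extracellular matrix and from 0.341 to 0.984 for the others. Single libraries moved several of these lists past the threshold or turned their direction. Neutrophil markers passed, higher, without control 1 (0.00933), control 2 (0.0185), control 3 (0.0252) and restraint 1 (0.000127). Extracellular matrix passed, lower, without restraint 2 (1.51e-07, median -0.47 against -0.059), and had a median of 0.14 without restraint 1. Schwann markers passed, lower, without restraint 3 (0.000406, median -0.82 against -0.15) and control 1 (0.0141), and had medians of 0.070 without control 2, 0.014 without restraint 1 and -0.0054 without restraint 2. Cell cycle genes passed, higher, without restraint 1 (0.00161, median 1.03 against 0.43), and had a median of -0.059 without restraint 2. Adipocyte markers passed, lower, without control 1 (0.0141, median -0.35 against -0.12), and had medians of 0.021, 0.033 and 0.019 without control 2, control 3 and restraint 3. None of the values in the opposite direction passed.

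In the sample structure the first principal component held 36.9% of the variance and parted the groups: controls lay between -31.5 and -24.7, and restraint 1, 2 and 3 at 11.8, 43.0 and 32.8. The second held 22.7% and spread both groups, with control 2 at -32.4 and control 3 at 35.1. Spearman correlations between libraries ran from 0.972 to 0.989. Across the lists, camera with a preset correlation called 16 of 36, 12 higher and 4 lower. None passed with an estimated correlation, where the smallest adjusted p was 0.283. The 7 lists called by fry were atrophy, immediate early, denervation and junction, heat shock, cyclic AMP and unfolded protein genes, higher, and interferon-stimulated genes, lower. Other splits of the 6 libraries into groups of 3 called up to 17 lists with the preset correlation, and at most 3 features.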

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

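The count of 282 calls rose to 809 with the DESeq2 Wald test and fell to 153 and 155 with limma on log2(FPKM + 1) and log2(FPKM + 0.1), 122 and 112 with log2(TPM + 1) and log2(TPM + 0.1), and 137 with a minimum fold of 1.2; with each library left out it ran from 16 to 350. FPKM and TPM tested fewer features; otherwise the cause was not tested. In simulated counts DESeq2 made more calls than edgeR, both true (78.5% against 60% of 2-fold changes recovered) and false (31 against 12). Scaling, filter, voom, robust dispersion and feature removal kept the count within 1.5 times. Every one of the 282 calls kept its sign under each alternative that tested it. None had overlapping groups, so leaving out a library could hardly turn a sign. Sizes did move: under alternatives that kept all libraries, Nr4a3 went from 4.28 to as low as 2.22 on the log2 scale. Foxo6 went from -1.93 to as little as -1.13. Higher calls were 69.1% (Wilson 95% interval 63.5% to 74.3%). That interval treats the calls as independent and does not measure the spread between libraries. The share was 61.8% with upper quartile factors, 61.9% with DESeq2 and 74.8% with log2(FPKM + 0.1). It was 81.1% and 82.1% with TPM and a pseudocount of 1 or 0.1, and 67.2% to 81.8% with each library left out. The cause was not tested. Of the 36 lists camera called 16, with an estimated correlation 0, and fry called 7, of which 6 were among the 16; with each library left out the count was 13 to 18. With the replicate block 60 features were called, 86.7% of them higher, and 14 lists, without glycolysis (adjusted p = 0.0563) and the tricarboxylic acid cycle (0.0643). Libraries of the same number deviated from their group means with correlations of 0.0137, -0.201 and -0.209. Control 2 with restraint 3 gave 0.22 and control 3 with restraint 2 gave 0.202. These values show no pairing by number, but so few libraries cannot exclude a shared batch or day. With each library left out, the log2 fold change of Ccl2, not called, ran from -0.17 to 0.32 (negative without control 3 and without restraint 3, at -0.076) and that of Alas2, not called, from -0.57 to 0.075 (positive without control 3). Depth limits genes near the floor, such as Il6.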

Other observations

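All genes and tests in this part were chosen after the values were seen. Several single genes outside the fixed lists were among the calls; no group they might form was tested. Xirp1, an actin-binding repeat protein of muscle, rose from 73.5 ± 17.5 to 338 ± 52.7 CPM (n = 3 per group) with an edgeR adjusted p of 0.0032. Abra, an actin-binding protein of striated muscle, rose by 1.54 ± 0.14 on the log2 scale; both were called in each of the 6 fits with a library left out. Slc38a2, an amino acid transporter, rose by 1.25 ± 0.14, a call lost without control 1 (edgeR adjusted p = 0.0689). Flnc, filamin C, rose by 1.42 ± 0.21, a call kept only without control 3 and without restraint 1. Gbp7 and Iigp1, GTPases known to be induced by interferon, fell by 1.05 and 1.24 on the log2 scale. The call of Gbp7 was lost without control 1 (0.108), control 2 (0.0512) and restraint 3 (0.0578), and that of Iigp1 without control 1 (0.113), restraint 2 (0.0545) and restraint 3 (0.0738).

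The real split of the libraries called 282 features and the highest of the other splits 3. For gene lists the real split called 16 and the highest other 17, and 3 of the 10 splits, the real one included, called at least 16. For features, 1 split reached 282, the real one. With 10 splits a share under 0.05 cannot be reached in either case.

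Restraint 1 lay nearer to the controls than restraint 2 and 3. Over the 350 features called without it, it showed a median 0.504 of their change, with quartiles of 0.209 and 0.759, against 1.04 for restraint 2 and 1 for restraint 3 over their own left-out calls. A first test for a mislabelled control, a lower quartile above 0.25, was not met. A further test chosen after it found restraint 1 past all 3 controls in 89.1% of those features. Each left-out control was compared with the other 2, over 16, 51 and 174 features, and lay past them in at most 70.7%. On the first principal component of all tested features, restraint 1 lay at 11.8 and the controls between -31.5 and -24.7. These values and the 89.1% argue against a mislabelled control. The late choice of the further test and its unlike settings limit the weight of the 89.1%. Admixture of control RNA would lower all changes alike, but the median was 0.393 for higher and 0.729 for lower calls. That is a difference of -0.336 (bootstrap interval -0.444 to -0.248). The difference was 0.246 (0.0374 to 0.451) for restraint 2 and -0.00933 (-0.16 to 0.742) for restraint 3. Unequal shares thus arose in restraint 2 as well, and the bootstrap draws features within a library, so partial admixture is left open. Differences between animals in response also remain open and were not tested.

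The 10 clock genes grouped here with Nr1d1 by phase had a median log2 fold change of -0.77, 8 of them negative and 2 positive, and the 6 grouped with Arntl 0.81, 5 positive and 1 negative, a difference of 1.58. That difference was not tested, and 5 of the 19 genes of the clock list passed over all genes. Another time of day at tissue collection may give this pattern, and so may restraint; the labels give no collection time, so the explanations cannot be told apart.

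In 11 features every library of a group had 0 counts and every library of the other at least 10, 9 of them counted in restraint; the highest of the other splits gave 5. The largest limit, at least 79.8-fold higher in restraint against a floor of 3 counts per library, was that of the unannotated locus MSTRG.707. It was called in each of the 6 fits with a library left out. Sprr1a, a small proline-rich protein, was at least 12.8-fold higher in restraint and Mymx, the fusion peptide myomixer, at least 16.9-fold. The limits of Sprr1a and Mymx rest on group means, and in restraint 1 each gene had only 10 counts (0.225 CPM). Without restraint 2 these limits were 8.91-fold and 10.5-fold, and with a library left out edgeR called both genes only without restraint 1. Reads assigned among overlapping genes could give such features, but 4 of the 9 with coordinates overlapped another gene, or 44.4% (exact 95% interval 13.7% to 78.8%), against 47.2% of 4616 others of like abundance (Fisher exact p = 1, two-sided). With 9 features and so wide an interval, the Fisher test cannot exclude an excess of overlap. Sprr1a and Mymx overlapped no other gene with coordinates, so overlap among such genes is not the source of all of them. Unannotated loci had no coordinates, so overlap with them was not examined. Near-identical copies elsewhere in the genome were not examined either.

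Srxn1, the antioxidant enzyme sulfiredoxin, rose by 1.58 ± 0.12 on the log2 scale and Bach1, a repressor of antioxidant genes, by 1.04 ± 0.13; the call of Bach1 was lost without control 1 (edgeR adjusted p = 0.0831) and control 2 (0.0512). A wider response of NRF2 targets may be a hypothesis: 23 tested targets had a median log2 fold change of 0.17 and a camera p of 0.018 with an estimated correlation (a model fitted with limma), or 0.0309 without Srxn1, and the smallest p of the other splits was 0.287. Only Srxn1 passed alone over all genes, and this p is not adjusted for the 36 lists tested before it.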
